A study of Mus musculus with 2 samples.

How the data were processed

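Jejunal cells of mice with the Lgr5-eGFP-IRES-CreER allele had been sorted for GFP and captured with droplet-based 3' chemistry (10x Genomics Chromium), per the labels. The labels give 3 female mice of 10 to 12 weeks per condition and 1 library for each of the conditions, Fc control and FZD5/8 antagonist. Dose and duration are not given in the sources used here, and no label ties a cell to a mouse, so each group counted as 1 sample. The deposited matrices hold UMI counts per gene and barcode, not normalized. They had been made with Cell Ranger on GRCm38 (mm10), per the submitters' processing notes, and the file headers give software version 3.1.0. Every deposited barcode had 500 or more UMIs. How barcodes were chosen, and the annotation release, are not given in the sources used here. The reporter sequence is not among the 31053 genes of the files.

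The control library held 67411637 UMIs in 12672 barcodes and the antagonist library 55810293 UMIs in 13085. Cells with at least 500 genes and at most 20% of UMIs from mitochondrially encoded genes were kept, 11263 (88.9%) and 11019 (84.2%). Scrublet, as implemented in scanpy 1.11.5 with an expected doublet share of 10%, called 0 cells in each library and was taken not to have worked, so doublets remained. Counts were scaled to 10000 per cell and log-transformed. Both libraries were clustered together on 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1.0.

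Marker genes for 15 cell classes, 30 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule that turns markers into names was set afterwards. A marker counted where its level was at least 1.5 times that of the other cells, at least 5% of the cluster's cells had it, and it reached 20% of its highest cluster. A name needed at least 3 such markers and 33% of those measured. A cluster stayed unnamed where its median UMI count was under 1/3 of that of its own library with no marker among its 10 leading genes, or where markers of another class outnumbered its own there. This left 11 named and 5 unnamed clusters, and none was named as a non-epithelial type, so all kept cells entered the comparisons.

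UMIs were summed per library, over all cells or within a class, and divided by the library's or class's total to give CPM. Levels have exact 95% Poisson intervals, ratios exact conditional binomial intervals and shares of cells exact (Clopper-Pearson) binomial intervals. A count of 0 was given a floor of 3 counts. No test was made. Named genes were those with at least 50 CPM in a library and 100 UMIs over both, without unnamed gene models, mitochondrially encoded, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes. Of these the 12 highest and 12 lowest ratios were taken in all cells, 8 and 8 in stem-like cells, and 4 and 4 in each other class with 100 cells in both libraries. Lgr5, Axin2, Ascl2, Olfm4, Smoc2, Mki67, Cdkn1a and the measured Fzd genes were always taken. Examples from a list were its 2 highest and 2 lowest members with 20 CPM or more in a library. Coordinates came from a GRCm38 annotation (GENCODE), which held 30934 of the 31053 gene identifiers.

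The lists covered Wnt targets, the Lgr5 stem cell signature, Wnt receptors, Wnt ligands, Notch, BMP, fetal and regenerative genes, S phase, G2 and M phase, absorptive enterocyte, villus-bottom, villus-tip, goblet, Paneth, enteroendocrine and tuft cell genes. They also covered MHC class II, interferon response, p53 response, apoptosis, unfolded protein response, dissociation, ribosomal proteins, Myc targets, mitochondrially encoded genes, oxidative phosphorylation, glycolysis, cholesterol synthesis, fatty acid oxidation and the Eph family. A list's value was the median log2 ratio of its members with 20 or more UMIs, with 0.5 added to each sum. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. For shares of cells with a UMI, each cell was thinned to 3000 UMIs.

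Ratios and intervals were tried on simulated Poisson counts for 13757 genes, drawn independently, 200 of them changed. These counts follow the model that the intervals assume. The results therefore check the calculation, and not how well it covers differences between cells or mice. The direction was recovered for 98.5% of genes changed 1.5-fold and for 100% of those changed 2-fold or 4-fold. The interval excluded equality for 80.6%, 97.0% and 100% of them and for 4.29% of unchanged genes. Of 100 simulated lists without change, 7 lay in the outer 5% of random lists, and 20 of 20 lists of doubled genes lay above them. Alternatives were other cell filters, resolutions, seeds and gene sets for clustering, centring each gene within its library, thinning, other scalings, equal weight for each cell, weighting cell classes alike, other limits on low counts and, chosen after seeing the data, leaving out classes, unnamed clusters or the 10% of cells with the highest doublet scores. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9 were used.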

Results

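Single-cell transcriptomes were profiled from epithelial cells of the mouse jejunum, sorted for the GFP reporter of Lgr5, the marker gene of crypt base stem cells. The mice carried the Lgr5-eGFP-IRES-CreER allele and were 10 to 12 weeks old, and the files hold 1 droplet library per condition, with 3 mice per condition. The conditions were an Fc control and an antagonist of FZD5 and FZD8, which are receptors for Wnt ligands. The comparison asks how crypt cells sorted by this reporter differ when these receptors are blocked. The Fc control library held 12672 barcodes with 67411637 UMIs, and the antagonist library 13085 barcodes with 55810293 UMIs. After filtering, 11263 control cells (median 4478 UMIs) and 11019 antagonist cells (median 2732 UMIs) remained. With 1 library per group there was no replicate check and no test. Every interval given for a level, a ratio or a share is a 95% interval that covers counting error only. Each comparison is therefore between these libraries, not between the conditions. Levels are given as CPM, a gene's UMIs scaled to the library's total of kept UMIs or, within a class or cluster, to its total.

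The libraries differed in sex-linked transcripts, although both are labelled female. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d together reached 106 CPM in the control library and 5.60 CPM in the antagonist library. Xist, the non-coding RNA that silences one X chromosome in female cells, was at 1.33 CPM in the control library and at 512 CPM in the antagonist library. The sex-linked transcripts and the condition therefore could not be separated in any comparison. The median log2 ratio of 152 X-linked genes with at least 20 CPM was -0.04, against -0.07 for 5667 autosomal genes.

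Transcripts of crypt base stem cells were lower in the antagonist library. Lgr5 (ENSMUSG00000020140, GRCm38 chromosome 10, 115450311 to 115587780) was counted 4385 times in the control library, 66.2 CPM (64.3 to 68.2), and 168 times in the antagonist library, 3.09 CPM (2.64 to 3.60). This was 21.4-fold lower (interval 18.4 to 25.1). Ascl2 (chromosome 7, 142966829 to 142969264), a transcription factor of stem cell identity, was 9.67-fold lower (8.70 to 10.8). Olfm4 (chromosome 14, 79984081 to 80023139), an abundant secreted stem cell marker, was 7.21-fold lower (7.10 to 7.32), at 2325 CPM against 323 CPM. Axin2 (chromosome 11, 108920349 to 108950783), a feedback inhibitor of Wnt signalling, was 4.63-fold lower (4.39 to 4.88), and Smoc2 was 1.98-fold lower (1.90 to 2.06).

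**Figure D1:**
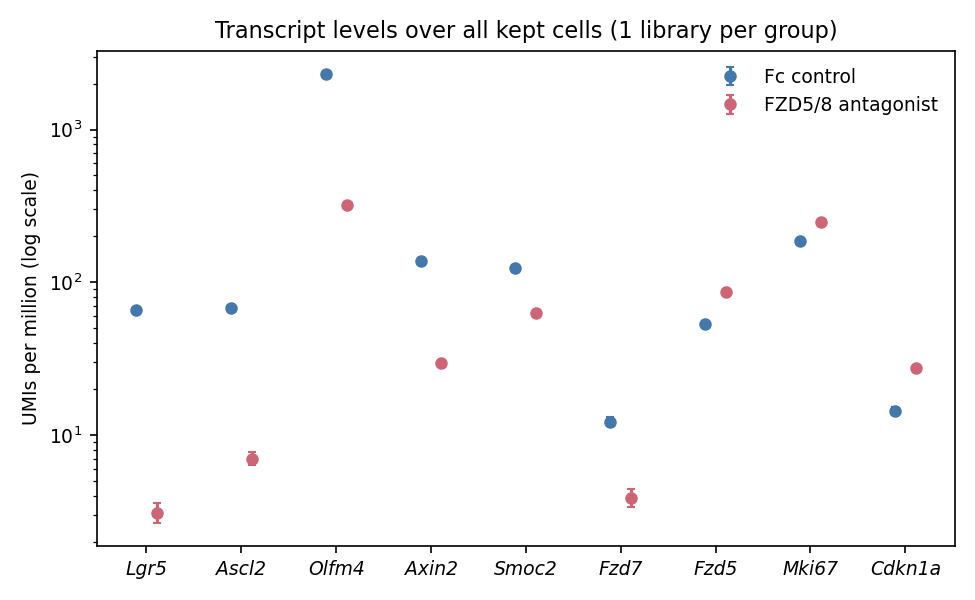
Level in CPM (log axis) of 9 genes over all kept cells of the Fc control library and the FZD5/8 antagonist library; points are library values and bars are exact 95% Poisson intervals, which cover counting error only. Lgr5 was at 66.2 CPM in the control library and 3.09 CPM in the antagonist library, while Fzd5 was at 53.7 and 86.2 CPM.

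Among the 2866 genes considered by size, the 12 with the lowest ratio were Lgr5, Rgcc, Ascl2, Agr3, Gkn3, Sorbs2, Olfm4, Lbh, Igfbp4, Soat1, Tifa and Rgmb, from 21.4-fold to 5.15-fold lower in the antagonist library. Rgcc was at 71.2 CPM in the control library and at 6.42 CPM in the antagonist library, and Gkn3 at 146 and 17.1 CPM. The 12 with the highest ratio were Xist, Rbp7, Car4, Arg2, Dmbt1, Zg16, Coro2a, Clca1, Cox7a1, Chp2, Insig1 and St3gal4. Apart from Xist, these ratios ran from 4.96 for Rbp7, a retinol-binding protein, to 2.88 for St3gal4. Dmbt1, a secreted mucin-like scavenger receptor of the gut lining, was the most abundant of them, at 1080 CPM in the control library and 3803 CPM in the antagonist library, a ratio of 3.52 (3.49 to 3.55). Zg16 and Clca1, products of goblet cells, had ratios of 3.18 (3.13 to 3.22) and 3.05 (2.87 to 3.24). Without the differentiated classes, chosen after seeing the data, which leaves the unnamed clusters in, their log2 ratios were 6.09 and 5.77, against 1.67 and 1.61. For St3gal4 the log2 ratio was 1.53, with 0.76 when cell classes were weighted alike and 3.00 without the differentiated classes, and for Rbp7 it was 2.31, with 1.68 under the weighting.

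The Wnt target list and the Lgr5 stem cell signature were lower as groups. Of 23 measured Wnt target genes, 22 had a lower level in the antagonist library, 19 of them by 1.5-fold or more, and the median log2 ratio was -1.65. The exception was Kremen1 (4.59 and 5.32 CPM), named after its values were seen. All 35 measured members of the stem cell signature, which shares 10 genes with the Wnt target list, were lower, 32 of them by 1.5-fold or more, with a median of -1.58. Both medians were at percentile 0 of 10000 random lists of the same size matched on mean expression, as a description of these libraries. The members that differed least were Ccnd1 among the Wnt targets (159 CPM and 139 CPM) and Urah in the signature (29.4 and 26.3 CPM). Weighting the cell classes alike in both libraries left Lgr5 at a log2 ratio of -2.75, against -4.42 without the weighting. Olfm4 was at -1.65 against -2.85, Ascl2 at -1.63 against -3.27, Axin2 at -1.41 against -2.21, Rgcc at -1.90 against -3.47 and Gkn3 at -2.07 against -3.09. The unnamed clusters entered this weighting as a single class. Cluster 5, described below, held 2146 of the 2488 control cells in that class but 49 of the 6589 antagonist cells. The weighting therefore did not make composition alike, and these values are not free of it.

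The transcripts of the receptors differed in both directions. Fzd5 (chromosome 1, 64730558 to 64737751), one of the receptors that the antagonist blocks, was at 53.7 CPM in the control library and 86.2 CPM in the antagonist library, a ratio of 1.61 (1.54 to 1.68). Fzd8 was rare, with 84 and 57 UMIs, and its ratio of 0.827 (0.580 to 1.17) had an interval that included equality and turned to a log2 ratio of 0.10 in thinned cells. Fzd7 was 3.15-fold lower (2.70 to 3.68), Fzd2 was 3.69-fold lower (2.90 to 4.74) and Fzd6 was 2.27-fold lower (1.93 to 2.70). Fzd1 and Fzd4 had intervals that included equality, and Fzd3 and Fzd9 had at most 38 UMIs in either library. Over the 15 measured receptors and co-receptors the median log2 ratio was -0.56, at percentile 0.77. Of the Wnt ligands, 8 were measured, with a median of -0.84 at percentile 5.30 that kept its direction in 12 of 13 alternatives (-1.97 to 0.04), and Wls, which carries Wnt proteins to the cell surface, was at 55.1 and 48.1 CPM.

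Shares of cells with a UMI differed in the same directions at equal depth. With every cell thinned to 3000 UMIs, which left out 3727 control and 5983 antagonist cells, 18.7% of control cells and 0.774% of antagonist cells had an Lgr5 UMI. Without thinning the shares were 27.2% and 1.44%. No cluster was named as non-epithelial, the planned measure of free RNA, so enterocyte-like cells, which should lack Lgr5, stood in for it, with median depths of 9181 and 4299.5 UMIs. Their thinned shares were 0.930% (0.113 to 3.32) in the control library and 0 of 423 cells in the antagonist library. The exact interval of the latter reaches 0.868%, and the floor of 3 counts is 0.709%. Without thinning the shares were 6.28% and 0 of 602 cells, with an exact interval up to 0.611% and a floor of 0.498%. Ascl2 was found in 18.9% and 1.85% of thinned cells, Axin2 in 33.6% and 7.63%, and Olfm4 in 91.0% and 40.0%. Thinned enterocyte-like cells had Ascl2 in 1.40% and 0.236% and Axin2 in 4.65% and 1.42%. Olfm4 was also found in 32.6% of enterocyte-like control cells and 10.6% of enterocyte-like antagonist cells, as free RNA or their own, which was not tested. Mki67, a marker of cycling cells, was found in 30.4% of thinned control cells and 40.8% of thinned antagonist cells, and Fzd5 in 15.5% and 22.7%. Without thinning these shares were 37.6% and 40.5% for Mki67 and 23.8% and 26.8% for Fzd5. In thinned enterocyte-like cells they were 6.05% and 8.98% for Mki67, and 18.6% and 22.7% for Fzd5, about as often as in all cells.

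Transcripts of the G2 and M phases were higher in the antagonist library. Mki67 was at 187 CPM in the control library and 247 CPM in the antagonist library, a ratio of 1.32 (1.29 to 1.35). Of 52 measured genes of the G2 and M phase list, 49 were higher in the antagonist library, 5 of them by 1.5-fold or more, with a median log2 ratio of 0.33 above all random lists. The S phase list had a median of 0.11 at percentile 99.91, with 25 of 42 genes higher, E2f8 (22.6 and 46.5 CPM) at one end and Cdca7 (339.5 and 118 CPM) at the other. Its median was -0.20 without the unnamed clusters, an alternative chosen after seeing the data. Cdkn1a, an inhibitor of the cell cycle, was at 14.4 and 27.4 CPM, a ratio of 1.91 (1.76 to 2.07), a log2 ratio of 0.93 that was 2.09 without the differentiated classes.

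Transcripts of absorptive cells were higher in the antagonist library. Of 35 measured members of the absorptive enterocyte list, 31 were higher, 25 of them by 1.5-fold or more, and the median log2 ratio was 0.78, above all random lists. Enpep, a brush-border peptidase, was at 12.1 and 38.2 CPM, and Maf at 16.2 and 43.0 CPM, while Dpp4 was at 99.5 and 83.6 CPM. The villus-bottom absorptive list had a median of 0.63, with Gsdmc4 at 4.82 and 36.7 CPM and Dmbt1 among the higher members. The antimicrobial lectins Reg3b (1355 and 333 CPM) and Reg3g (1470 and 404 CPM) of the same list were lower. The villus-tip list had a median of -0.25 at percentile 14.16 (13 of 14 alternatives in the same direction), with Creb3l3 at 17.1 and 37.4 CPM and Ceacam1 at 153 and 87.9 CPM. With cell classes weighted alike, which left the make-up of the unnamed class unlike, the enterocyte median was 0.31 and the G2 and M phase median 0.08.

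**Figure D2:**
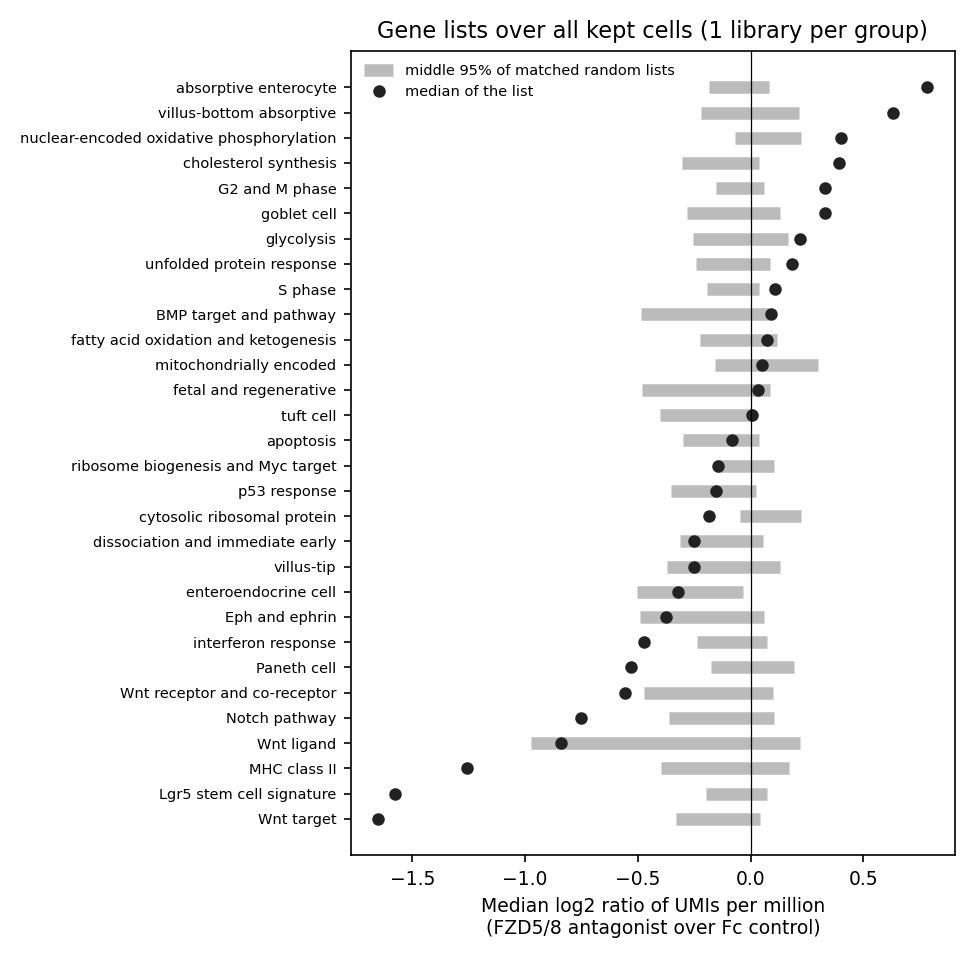
Median log2 ratio of CPM (FZD5/8 antagonist over Fc control, horizontal axis) of 30 gene lists over all kept cells; points are list medians and grey bars the middle 95% of 10000 random lists of the same size matched on mean expression. The Wnt target list (-1.65) and the Lgr5 stem cell signature (-1.58) lie lowest and the absorptive enterocyte list (0.78) highest.

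Clustering gave 16 clusters, 11 of which carried enough markers for a name. Stem-like cells (clusters 2, 3 and 12) made up 49.8% of control cells (48.8 to 50.7) and 1.89% of antagonist cells (1.64 to 2.16). These sizes rest on genes that differ between the libraries. When the Wnt target, stem cell and cell cycle lists were left out of the clustering, the shares were 52.8% and 2.67%, and when each gene was centred within its library they were 22.5% and 2.28%. Cluster 12 of this class was led by Reg3b, Reg3g and MHC class II genes. The 5 unnamed clusters held 22.1% of control cells and 59.8% of antagonist cells under a naming rule that was set after the data were seen. Each was mostly of 1 library, as were the stem-like clusters 2, 3 and 12 (97.9%, 95.3% and 94.0% control cells) and the cycling clusters 7 (94.0% control cells) and 4 (93.1% antagonist cells), so that a cluster can stand for a library and not for a cell type. Cluster 1, led by Dmbt1 and genes of DNA replication such as Uhrf1, held 209 control and 2730 antagonist cells. Cluster 5, led by Sorbs2 and mitochondrial transcripts, held 2146 and 49. It had 9 of 14 stem cell markers, with Lgr5 at 105 CPM, and was unnamed for its low depth, so that 19.1% of control cells with these transcripts lie outside the stem-like share. Cluster 8, led by goblet cell genes such as Zg16 and Clca1, held 10 and 1041. The antagonist cells of cluster 8 had a median of 9382 UMIs, against 2732 for the library, and the cluster also had the Paneth cell gene Lyz1 at 812 CPM and the enterocyte gene Apoa1 at 262 CPM, with no doublets removed. Cluster 6, led by immunoglobulin genes such as Igkc (298 CPM over the cells of both libraries), held 65 and 1996 cells. The markers of B and plasma cells had 1604 UMIs (24.2 CPM) in the control library and 204 UMIs (3.75 CPM) in the antagonist library. The immunoglobulin lead may therefore rest largely on the 65 control cells, and cannot be taken to describe the 1996 antagonist cells. Igkc in this cluster was not split by library. The antagonist cells of cluster 6 were shallow, with a median of 1265.5 UMIs. Cluster 10, with Xist and mitochondrial transcripts among its leading genes, held 58 control and 773 antagonist cells. Its antagonist cells had medians of 1076 UMIs and 12.1% mitochondrial UMIs, against 1311 and 11.7% in the control cells of cluster 5. Shallow cells thus lay in unnamed clusters of both libraries.

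Cycling progenitor-like cells made up 16.8% of control cells (16.1 to 17.5) and 21.4% of antagonist cells (20.7 to 22.2), but different clusters held them: cluster 7 had 1726 control and 110 antagonist cells, and cluster 4 had 167 and 2252. Enterocyte-like cells were 2.12% of the control library (1.86 to 2.41) and 5.46% of the antagonist library (5.05 to 5.90). Goblet-like cells were 4.61% (4.23 to 5.01) and 3.23% (2.91 to 3.58). Tuft-like cells were 2.50% and 2.52%, and enteroendocrine-like cells 1.14% and 0.889%, with overlapping intervals. Paneth-like cells were 0.968% (0.795 to 1.17) and 4.77% (4.38 to 5.19), with a median of 21410 UMIs in the control library and 2989.5 in the antagonist library. Among cells of named clusters alone, chosen after seeing the data, the shares were 21.6% and 53.3% (cycling progenitor-like), 2.72% and 13.6% (enterocyte-like), 5.91% and 8.04% (goblet-like, the opposite direction), 3.21% and 6.28% (tuft-like), 1.46% and 2.21% (enteroendocrine-like, also opposite) and 1.24% and 11.9% (Paneth-like). The difference in the tuft-like share kept its direction in 6 of 10 alternatives (-1.24 to 3.06 percentage points). The sort on the reporter and the depth gap can both set these shares.

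**Figure D3:**
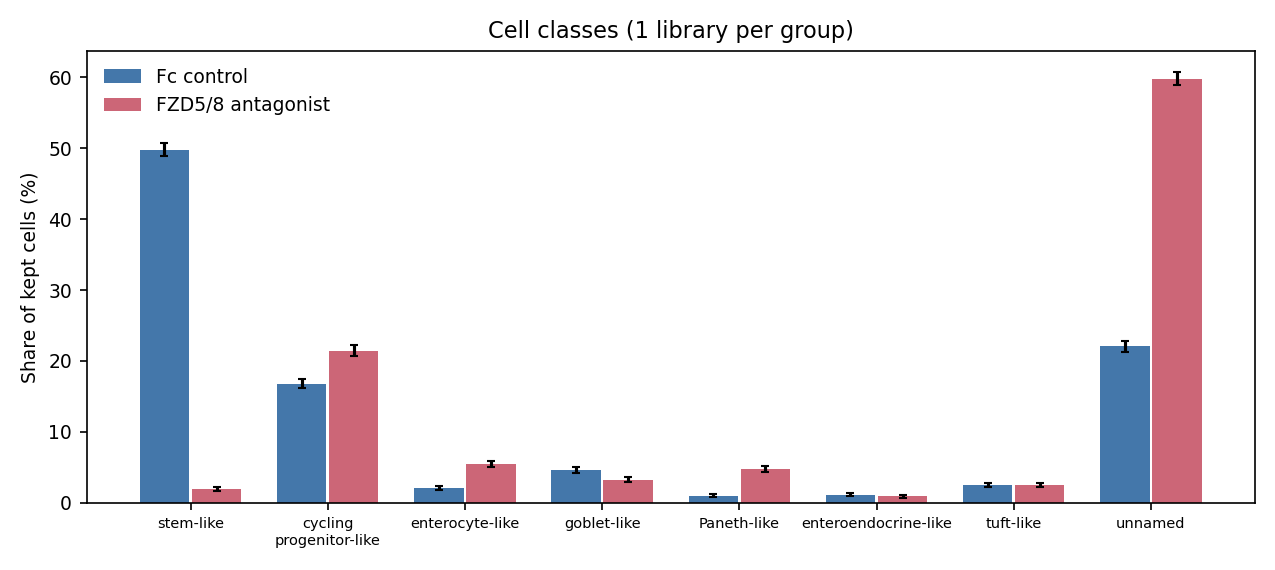
Share of kept cells (%, vertical axis from 0) in each cell class of the Fc control and FZD5/8 antagonist libraries; error bars are exact 95% binomial intervals. Stem-like cells were 49.8% of the control library and 1.89% of the antagonist library, and unnamed clusters held 22.1% and 59.8%.

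Within the stem-like class, which had 5605 control and 208 antagonist cells, stem transcripts were lower by smaller factors. The class was named by these same markers, so smaller factors are in part built in. Clusters 2, 3 and 12 held 2721, 2318 and 566 of its control cells and 57, 115 and 36 of its antagonist cells. These clusters had Lgr5 at 110, 70.3 and 77.1 CPM, so their unlike shares enter the ratios. Lgr5 was at 90.1 CPM in the control cells and 30.6 CPM, from 22 UMIs, in the antagonist cells, 2.94-fold lower (1.94 to 4.71). Olfm4 was 1.57-fold lower (1.49 to 1.66), Axin2 1.33-fold lower (1.08 to 1.66) and Smoc2 1.28-fold lower (1.03 to 1.60), while the interval for Ascl2 included equality. The stem cell signature had a median log2 ratio of -0.49 and the Wnt target list of -0.43, both at percentile 0. In the class built without these lists, which was still named by stem cell markers, the medians were -0.90 and -0.79. The S phase, G2 and M phase and absorptive enterocyte lists had medians of 0.30, 0.39 and 0.49, each above all random lists. The 8 genes with the lowest ratio were Rnase1, Mt2, Gkn3, Lbh, Acot1, Lgr5, Utrn and Defa36, and the 8 with the highest were Xist, Zg16, Dmbt1, Rbp2, Zdhhc2, Bmp3, Elovl6 and Arg2. Mt2, a metallothionein, was at 248 and 69.5 CPM, and Zg16 at 10.0 and 90.4 CPM.

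In the cycling progenitor-like class, held by clusters 7 and 4 as above, Lgr5, Ascl2, Rgcc and Lbh had the lowest ratios, and Xist, Rbp2, Cox7a1 and Arg2 the highest. Lgr5 was at 58.3 CPM in control cells and 3.19 CPM in antagonist cells. The stem cell signature had a median of -1.43 and the Wnt target list of -1.42, both at percentile 0. The S phase and G2 and M phase lists had medians of -0.22 and -0.11 in this class, the opposite sign to all cells. Goblet-like cells had Olfm4, Gkn3, Defa36 and Marcksl1 as the lowest and Xist, Rbp2, Gsta4 and Gsta1 as the highest. Enterocyte-like cells, of which cluster 15 held 143 control and 198 antagonist cells and cluster 14 held 96 and 404, with Apoa1 at 11720 and 959 CPM in these clusters, had Zg16, Reg3b, Defa22 and Olfm4 as the lowest and Xist, Pck1, Pclaf and Dmbt1 as the highest. Tuft-like cells had Reg3b, Reg3g, Gkn3 and Olfm4 as the lowest and Xist, Zg16, Apoa1 and Rbp2 as the highest. In Paneth-like cells the Paneth cell list took 77.5% of UMIs in the control library and 51.8% in the antagonist library, and the median log2 ratio of all genes was 1.84, against which ratios in this class are to be read. Mmp7, a protease that activates defensins, was at 1259 and 348 CPM there, and Reg3g, Ccl9 and Defa27 were also lowest. The highest there were Gsta1, Xist, Rbp2 and Fabp1. Gsta1 was counted 0 times in the control library and 190 times in the antagonist library, 88.2-fold higher when the 0 is set to the floor of 3 counts. Fabp1, a fatty acid carrier of enterocytes, was at 5.87 and 521 CPM.

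Lists of secretory cells differed from each other. The goblet cell list had a median log2 ratio of 0.33 at percentile 99.99, with 14 of 19 genes higher. The Paneth cell list had a median of -0.53, with 22 of 23 genes lower, Mmp7 at 125 and 58.7 CPM and Gm14851 at 4100 and 3755 CPM. Its median was 0.74 without the Paneth-like class, also chosen after seeing the data, and 0.16 in thinned cells. Within the stem-like and cycling progenitor-like classes it was -0.89 and -1.90. In every class the median cell had a lower share of its UMIs from this list in the antagonist library (unnamed clusters: 2.63% and 0.878%). The 0.74, from summed UMIs, therefore does not describe the median cell of any class. The tuft cell list had a median of 0.00 and the enteroendocrine cell list of -0.32 at percentile 30.14, with Gcg at 30.7 and 2.19 CPM and Nts at 0.514 and 21.8 CPM. The sign of the tuft and enteroendocrine medians turned under other choices of cells. The Notch pathway list had a median of -0.75 at percentile 0, with Olfm4 and Hes6 (54.3 and 22.7 CPM) among its lower members and Neurl3 (39.8 and 45.4 CPM) among its higher ones. The BMP list had a median of 0.09 at percentile 97.85, with Id3 at 61.3 and 74.1 CPM and the direction kept in 11 of 14 alternatives (-0.15 to 0.22), and the Eph and ephrin list of -0.37 at percentile 11.90, with Efna4 at 31.1 and 10.9 CPM and Efnb1 at 31.8 and 42.9 CPM.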

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

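All tests in this part were chosen after the results they bear on had been seen.

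Both libraries are labelled female, and sex-linked transcripts differed between them. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d summed to 106 CPM in the control library, far above the 0.0453 CPM that a count of 0 allows. Xist was at 512 CPM in the antagonist library against 1.33 CPM in the control library.

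For this sex-linked pattern, RNA carried over from the antagonist library cannot account for the Y-linked transcripts in the control library, because their level in the antagonist library was 0.0526 of that in the control library (interval 0.0468 to 0.0590). A Xist UMI was found in 0.398% of control cells at equal depth, against 64.0% of antagonist cells, which is consistent with a control library made from male mice and an error in its label. Of the antagonist cells with a Y-linked UMI at equal depth, 24.6% (15.1 to 36.5) also had a Xist UMI, against 61.0% expected from other cells of the same clusters, and without thinning the share was 53.4% (47.2 to 59.5), against 67.4% of cells with no Y-linked UMI. Free or carried-over RNA alone as the source of those UMIs is argued against by these values, less strongly without thinning, and a small share of male cells in the antagonist library stays open. No label per mouse allows a further test.

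The lower stem cell and Wnt target transcripts in the antagonist library were also seen in cells thinned to 3000 UMIs. The Wnt target list had a median log2 ratio of -1.71 there, against -0.44 to -0.00 for the middle 95% of random lists. CPM is already scaled to totals, so thinning could move this value only through the weights of cells and the shallow cells left out. It shows that the difference was present among the deeper cells. It cannot exclude a depth-linked loss of cells. For a uniform excess of every other cell type, the absorptive enterocyte and tuft cell lists were compared over all cells. The median log2 ratio of the former lay 0.78 (0.58 to 1.14) above that of the latter. With the same weight for every cell it lay 0.57 (0.28 to 1.02) above it. Both intervals are 95% intervals over list members, not counting intervals. The enterocyte median was also 0.80 within the cycling progenitor-like class, so the gap can arise within cells. It therefore cannot decide whether every other cell type was in excess alike, and an excess of all or some cell types stays open. The sex of the mice cannot be told apart from the treatment, because Xist was 385-fold higher in the antagonist library and each condition has 1 library. The FZD5/8 antagonist, mouse-to-mouse differences and cell handling stay open as well.

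The higher share of Paneth-like cells in the antagonist library was not accounted for by free RNA spread alike over droplets or by depth. Even with all Paneth list UMIs of that library taken as free RNA, 89.0% (86.0 to 91.5) of its 526 Paneth-like cells had more of them than the highest of all its cells would (287 UMIs if spread alike). Droplets that hold Paneth cell material together with another cell are a candidate explanation. Transcripts of the absorptive enterocyte list were at 0.913 of their level in the other antagonist cells, against 0.166 for the same ratio in the control library. A difference in Paneth cells themselves stays open.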

How the results depend on the processing

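Leaving out classes, unnamed clusters or cells with the highest doublet scores, and shares among named clusters, were chosen after the data were seen. The other alternatives were fixed before the data were examined. The Wnt target median kept its direction in 14 of 14 alternatives (-1.76 to -1.28), the stem cell signature in 14 of 14 (-1.81 to -1.20), the log2 ratio of Lgr5 in 12 of 12 (-4.81 to -2.75) and the difference in the stem-like share in 10 of 10 (-64.7 to -20.2 percentage points, antagonist minus control). The cause of the differences between settings was not tested. Below, a change of sign is marked as reversed only where the interval of the main value excluded equality. For list medians this interval is taken over list members. Unmarked values can also have changed sign. Weighting the cell classes alike (the mean class composition) took the unnamed clusters as a single class, whose make-up differed between the libraries. Low numbers limit the values of Fzd8 (84 and 57 UMIs) and of the 208 stem-like antagonist cells, among others. Keeping called doublets could not differ, because none was called, and including non-epithelial clusters could not differ, because none was named. No paired analysis was possible because each group has 1 library. Scaling by the median of ratios moved the median log2 ratio of all genes from -0.01 to 0.12, and values under it are to be read against that shift. Of the values of single genes other than Lgr5, 251 stayed within their counting interval, 157 moved beyond it and none changed direction beyond it.

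The following are differences in percentage points in the share of stem-like cells, share of cycling progenitor-like cells, share of enterocyte-like cells, share of goblet-like cells, share of Paneth-like cells, share of enteroendocrine-like cells and share of tuft-like cells. With the loose cell filter they were -64.7 (stem-like), 3.19 (cycling progenitor-like) and -0.735 (goblet-like). With the strict filter they were -30.6, 18.2 and -2.60 for these classes, 4.24 for enterocyte-like and -1.01 for tuft-like cells. The enterocyte-like value was 2.69 at resolution 0.5 and the stem-like value -35.9 at resolution 1.5. Clustering without stem, Wnt and cycle genes gave -50.1 (stem-like) and 4.41 (enterocyte-like), and centring per library -20.2 (stem-like) and 11.2 (cycling progenitor-like). Thinned cells gave -46.4 (stem-like), 34.6 (cycling progenitor-like), 5.87 (enterocyte-like) and -1.24 (tuft-like). Among named clusters alone the values were -59.2 (stem-like), 31.7 (cycling progenitor-like), 10.9 (enterocyte-like), 2.12 (goblet-like, reversed), 10.6 (Paneth-like), 0.754 (enteroendocrine-like) and 3.06 (tuft-like).

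Median log2 ratios over all cells were as follows. The strict filter gave -0.70 (Paneth), -0.44 (tuft) and 0.21 (mitochondrially encoded). Thinned cells gave 0.97 (enterocyte), 0.16 (Paneth, reversed), -1.11 (enteroendocrine), -0.78 (tuft), -0.34 (ribosomal protein), -0.23 (Myc target) and -4.81 for Lgr5. A total without mitochondrial and ribosomal protein genes gave 0.36 (oxidative phosphorylation). The median of ratios gave 0.47 (G2 and M phase), 0.14 (tuft), -0.049 (ribosomal protein), 0.54 (oxidative phosphorylation) and 0.53 (cholesterol). Equal weight for every cell gave 1.10 (enterocyte), 0.84 (goblet), -0.060 (Paneth), 0.20 (enteroendocrine, reversed), 0.53 (tuft), -0.27 (ribosomal protein), -0.29 (mitochondrially encoded) and 0.50 (oxidative phosphorylation). The mean class composition gave -1.20 (stem cell signature), 0.079 (G2 and M phase), 0.31 (enterocyte), 0.81 (goblet), -0.70 (Paneth), 0.46 (enteroendocrine, reversed), 0.60 (tuft), -0.026 (ribosomal protein), -0.57 (mitochondrially encoded), 0.29 (cholesterol) and -2.75 for Lgr5. Without the unnamed clusters the values were -0.20 (S phase), 0.53 (G2 and M phase), 1.34 (enterocyte), 0.041 (Paneth, reversed), 0.42 (enteroendocrine, reversed), 0.68 (tuft), -0.46 (ribosomal protein), -0.37 (Myc target) and -4.08 for Lgr5. Without the Paneth-like class they were 0.74 (Paneth, reversed) and 0.37 (oxidative phosphorylation). Without the differentiated classes they were 1.49 (enterocyte), 3.01 (goblet), 1.28 (Paneth, reversed), 2.37 (enteroendocrine, reversed), 3.92 (tuft), 0.37 (oxidative phosphorylation) and 0.46 (cholesterol). Within the stem-like class built without stem, Wnt and cycle genes they were -0.79 (Wnt target), -0.90 (stem cell signature), -1.81 (Wnt ligand), 0.54 (G2 and M phase) and 0.91 (enteroendocrine).

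Differences in the share of cells with a UMI, in percentage points, were -10.6 (Lgr5), -16.5 (Axin2), -8.58 (Ascl2), -57.0 (Olfm4), 5.36 (Mki67) and 4.67 (Fzd5) with cells thinned to 1500 UMIs. Without thinning they were -25.7 (Lgr5), -36.0 (Axin2), -23.6 (Ascl2), 2.93 (Mki67) and 3.03 (Fzd5).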

Other observations

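Genes of respiration and sterol synthesis were higher in the antagonist library. All 37 measured genes of nuclear-encoded oxidative phosphorylation were higher, 5 of them by 1.5-fold or more, with a median log2 ratio of 0.40 above all random lists. Cycs, the electron carrier cytochrome c, was at 716 CPM in the control library and 1306 CPM in the antagonist library. The 13 mitochondrially encoded genes had a median of 0.05 at percentile 42.5, with mt-Nd1 at 1586 and 2111 CPM. Of 21 cholesterol synthesis genes, 20 were higher, with a median of 0.39, and Insig1, a regulator of sterol synthesis, was at 23.3 and 67.9 CPM. Glycolysis genes had a median of 0.22 at percentile 99.02, with Pfkp at 15.1 and 35.7 CPM and Hk2 at 73.5 and 34.2 CPM. Fatty acid oxidation and ketogenesis genes had a median of 0.07 at percentile 93.3, with Acot1 at 96.8 and 32.1 CPM and Ppara at 13.8 and 23.9 CPM.

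Genes of antigen presentation and of the interferon response were lower in the antagonist library. Of 8 measured genes on the MHC class II list, 7 were lower by 1.5-fold or more, with a median of -1.26 at percentile 0, and H2-Aa was at 60.7 and 21.4 CPM. Markers of B and plasma cells (24.2 and 3.75 CPM) and of myeloid cells (2.67 and 1.38 CPM) were lower too, and of these B cells and myeloid cells carry MHC class II. The myeloid markers had 177 and 75 UMIs, against 4020 and 1163 for H2-Aa. A part of these cells in the difference was not tested. The exception on the list was H2-T3, a class I-like gene that the list fixed in advance holds, at 32.6 and 36.3 CPM. The median of this list was -1.09 within the cycling progenitor-like class, -1.63 in goblet-like, -0.85 in enterocyte-like and -0.76 in tuft-like cells, and 0.07 in the stem-like class. Cluster 12 of the stem-like class, with MHC class II genes among its leading genes, held 36 of its 208 antagonist cells. It held a smaller part of the control cells, 566 of 5605, so the value of 0.07 also reflects the make-up of the class. Of 31 interferon response genes, 27 were lower, with a median of -0.47 at percentile 0, and Ifitm3 was at 1475 and 796 CPM.

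Stress and growth lists had medians closer to 0. The p53 response list had a median of -0.15 at percentile 53.4, with Trp53inp1 at 20.4 and 5.25 CPM, and the apoptosis list of -0.08 at percentile 74.4, with Bcl2 at 21.3 and 10.8 CPM. The unfolded protein response list had a median of 0.18 at percentile 99.9, with the chaperone-associated gene Sdf2l1 at 29.1 and 48.1 CPM. The dissociation and immediate early list had a median of -0.25 at percentile 9.53, with Jun at 83.7 and 35.5 CPM. Cytosolic ribosomal protein genes had a median of -0.18 at percentile 0, with 45 of 49 lower. Ribosome biogenesis and Myc target genes had a median of -0.14 at percentile 3.31, with Npm1 at 1351 and 926 CPM. Fetal and regenerative genes had a median of 0.03 at percentile 94.7, with Krt7 at 72.2 and 54.6 CPM and Anxa2 at 40.5 and 90.7 CPM, and the direction was kept in 8 of 14 alternatives (-0.27 to 0.17). Of the other lists here, the mitochondrially encoded median kept its direction in 10 of 14 alternatives, and the fatty acid oxidation, apoptosis and dissociation medians each in 13 of 14.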
